A study of Homo sapiens with 8 samples.

How the data were processed

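MicroRNA levels were measured on 8 single-colour arrays, 1 for each of 4 established breast cancer cell lines grown without trastuzumab and 1 for each grown with trastuzumab at 4 µg/mL. Total RNA was extracted with phenol and chloroform and labelled with the Hy5 dye of a miRCURY LNA labelling kit, per the labels' protocols. Those protocols also carry text on liver tissue and patients that matches none of the 8 samples.

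The values are log2 signals as deposited by the authors, 1 value per feature and array. The log base was read from the values, which run from 0 to under 16 as log2 of a scanner signal would. The scanner, the background correction, the normalization and the genome build are not given in the sources used here. The table held 929 features, of which 73 were empty on all 8 arrays and 0 were empty on some arrays only. The lowest value in every column was 0, which is a floor, and 205 of the 856 features with values stood at that floor on at least 1 array. The remaining 651 features were tested. The medians of these features differed between arrays by up to 0.77 log2, above the 0.5 set as the limit for keeping the deposited scale. Each array was therefore centred on the 75th percentile of the tested features and brought back to the common mean.

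The features carry mature microRNA accessions and no names, and the gene table used here holds no such accessions. No feature was therefore given a name. The rule allowed 10 features each way per comparison, and without names at most 2 higher and 2 lower are printed, and miR-26a and miR-30b, which the title of the series names, are not analysed here. The microRNA lists fixed beforehand could not be matched either, so the tests of lists were not run.

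Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The effect of trastuzumab across lines was fitted with cell line as a block, since both arrays of a line come from the same cell line by the labels. Over the 151 features with a mean log2 signal above 5, both arrays of a line correlated at 0.972 to 0.985 and arrays of different lines at 0.504 to 0.878. The effect in SKBR3 and BT474, the effect in MCF7 and MDA-MB-231 and the difference between these classes came from 1 fit over all 8 arrays. The classes follow background knowledge that SKBR3 and BT474 carry an amplified ERBB2 gene, and no label states them. MDA-MB-231 was set against the mean of the other 3 lines in a fit with cell line and treatment. The classes were set against each other on the mean of each line over its 2 arrays. Within a line there is 1 array per condition, so differences there have no test. The lines serve as the replicates of the treatment effect. Nothing in the labels speaks of repeated cultures. P-values of 1 line against the others therefore measure only the spread between single arrays of a line. Those of the classes against each other, from line means, measure the spread between lines.

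Features were named by a rule fixed before the data were examined. It takes the largest changes among those past the threshold that ran the same way in every line. Where too few passed, it takes the smallest p among features that ran the same way in every line. For a difference between classes or lines, this last condition was read as no overlap between both sides. Within a line it takes the largest rises and falls among features above the median level of 2.57. For want of names, only the first of these each way is printed. The alternatives were median centring, quantile normalization, the values as deposited, features above the median only, all 856 features with a value, log2 of the linear value plus 16, eBayes with trend and robust settings, a threshold of 0.10, no cell line block, and leaving out each line in turn. The limits of 5 and 8 on the mean log2 signal, the correlations between the responses of lines, and each line other than MDA-MB-231 against the rest were chosen after seeing the data.

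The pipeline was tested on simulated data with the level-dependent spread of the real arrays, 651 features, 200 of them changed, in 20 runs. For the effect across the 4 lines it recovered 27.9% of 2-fold, 76.8% of 4-fold and 96.2% of 8-fold changes, and 9.67% of its calls were false. For the effect in SKBR3 and BT474 it recovered 8.3%, 38.3% and 75.3%, with 6.34% of calls false. For MDA-MB-231 against the other lines it recovered 22.2%, 63.4% and 92.3%, with 10.7% of calls false. Each of these shares of false calls is above the nominal level. The simulation used the default eBayes settings, so the share of false calls with trend and robust settings is not known. In the simulation all features of a level shared 1 spread and 200 were changed, which may make calls easier than on the real arrays. The shares recovered may therefore not hold for the real arrays. There, MIMAT0000231 had a mean log2 difference of -3.55 across the 4 lines and was not called (limma adjusted p = 0.378). The number of arrays limits the precision of every value.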

Results

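MicroRNA levels were profiled in 4 human breast cancer cell lines with and without trastuzumab, a therapeutic antibody (Herceptin) against the ERBB2 (HER2) receptor. SKBR3 and BT474 are lines with an amplified ERBB2 gene, MCF7 is an oestrogen receptor-positive line without that amplification, and MDA-MB-231 is a mesenchymal-like line that lacks both. Each line was measured on 1 array without the antibody and on 1 array with it at 4 µg/mL, which gave 8 arrays. Of 929 features on the array, 651 had a signal above the floor on all 8 arrays. Most of these were dim, and 151 had a mean log2 signal above 5, that is above 32 on the linear scale. On the deposited scale, over all 856 features with values, the BT474 arrays were the brightest. They had 204 features above a log2 signal of 5 without and 199 with trastuzumab. The SKBR3 arrays were the dimmest, with 148 and 151. The MCF7 arrays had 165 and 158 such features and the MDA-MB-231 arrays 167 and 160. Features are given by their microRNA accession, since the table pairs none with a name.

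The first comparison asked which microRNAs changed with trastuzumab in all 4 lines. No microRNA passed the threshold in either direction. The smallest adjusted p was that of MIMAT0000231, which was lower with the antibody in 4 of 4 lines and whose log2 signal averaged 6.33 ± 1.53 (SD, n = 4 lines) without and 2.78 ± 1.36 with the antibody. Its mean log2 difference was -3.55 ± 1.19 (SD, n = 4 lines, limma adjusted p = 0.378), and the differences ran from -5.27 in SKBR3 to -2.57 in BT474. Next among the lower features, MIMAT0005942 had a mean log2 difference of -1.43 ± 0.42 (adjusted p = 0.485). On the other side, MIMAT0007348 had a mean log2 difference of 1.61 ± 0.45 and MIMAT0004606 of 2.19 ± 1.05 (adjusted p = 0.485 for both), and both were dim, with mean log2 signals of 2.04 and 1.98. With 16 added to the linear signal, the mean log2 difference was -2.06 for MIMAT0000231, -0.66 for MIMAT0005942, 0.40 for MIMAT0007348 and 0.50 for MIMAT0004606. In limma's fit with cell line as a block, 0 of 651 features passed the adjusted threshold. At an unadjusted p under 0.05 there were 46, of which 28 were higher and 18 lower, where 32.6 are expected by chance. Only 1 of the 46 was among the 151 brighter features, where 7.55 are expected by chance. In a limma fit of the 151 alone, chosen after the results were seen, 9 stood at an unadjusted p under 0.05. The low count of 1 therefore depends on the dim features in the fit. With a level-dependent, robust variance, 2 features passed, MIMAT0000231 (adjusted p = 5.27e-07, against 0.245 to 0.999 under the other alternatives) and MIMAT0005880, which had a mean log2 difference of 1.19 (adjusted p = 0.0406) but stood at -0.06 in MDA-MB-231. MIMAT0005880 lies outside the naming rule and was chosen after its values were seen. The level-dependent variance draws on other features of similar level, and its share of false calls was not simulated.

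Few features differed in one direction in all lines. Of the 651, 39 were higher with trastuzumab in every line and 38 were lower in every line, together 77, against 81.4 expected if the lines moved independently. Among the 151 brighter features, 6 were higher and 9 lower in every line, against 18.9 expected in all.

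The second comparison asked which microRNAs changed in the lines with amplified ERBB2. In SKBR3 and BT474 no feature passed the adjusted threshold. Among those that ran the same way in both lines, MIMAT0004606 had a mean log2 difference of 3.08 ± 0.37 (SD, n = 2 lines) and MIMAT0003280 of 2.40 ± 0.18 (limma adjusted p = 0.725 for both). On the lower side, MIMAT0007402 had a mean log2 difference of -2.62 ± 0.82 and MIMAT0000231 of -3.92 ± 1.91 (adjusted p = 0.725 for both). Of these 4, MIMAT0004606, MIMAT0003280 and MIMAT0007402 were dim, with mean log2 signals of 1.98, 1.74 and 2.44. With 16 added to the linear signal, the mean log2 differences were 0.73 for MIMAT0004606, 0.65 for MIMAT0003280, -0.66 for MIMAT0007402 and -1.99 for MIMAT0000231, and without SKBR3 that of MIMAT0000231 was -2.57. At an unadjusted p under 0.05 limma gave 41 features, 24 higher and 17 lower, against 32.6 expected by chance. With the level-dependent, robust variance, 3 features passed: MIMAT0000231, MIMAT0005880 and MIMAT0005898, of which MIMAT0000231 was lower (adjusted p = 0.00133, against 0.554 to 0.997 under the other alternatives) and the others higher.

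In MCF7 and MDA-MB-231, the lines without the amplification, no feature passed either. MIMAT0000723 had a mean log2 difference of 2.66 ± 1.35 (SD, n = 2 lines) and MIMAT0000091 of 1.72 ± 0.04, while MIMAT0004675 stood at -2.31 ± 0.42 and MIMAT0004514 at -2.24 ± 0.32 (limma adjusted p = 0.747 for each). All of these had mean log2 signals between 1.82 and 2.78. With 16 added to the linear signal, the mean log2 differences were 0.63 for MIMAT0000723, 0.54 for MIMAT0000091 and -0.84 for MIMAT0004675 and MIMAT0004514, and without MCF7 that of MIMAT0000723 was 1.70. At an unadjusted p under 0.05 limma gave 39 features, 23 higher and 16 lower, and 0 passed with the level-dependent, robust variance. The difference between the classes was tested directly. No feature passed, and 32 stood at an unadjusted p under 0.05, of which 14 changed more upward in SKBR3 and BT474. The smallest adjusted p of that test was 0.818.

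Within each line, between 32.1% and 38.1% of the tested features differed by more than 2-fold between the untreated and the treated array, nearly all of them dim. In BT474, 116 features were higher and 118 lower with trastuzumab, and in SKBR3 112 were higher and 133 lower. In MCF7 these numbers were 113 and 96, and in MDA-MB-231 141 and 107. On the scale as deposited the split was 88 higher and 142 lower in BT474 and 88 higher and 126 lower in MCF7. Among the 151 brighter features, only 9 passed 2-fold in BT474, 14 in SKBR3, 4 in MCF7 and 15 in MDA-MB-231. Of these, 7 of 9 were higher in BT474, 11 of 14 in SKBR3, 3 of 4 in MCF7 and 4 of 15 in MDA-MB-231. With 16 added to the linear signal, which damps dim features, the numbers past 2-fold among all 651 were 6, 31, 9 and 34 in the same order. With 1 array per condition, none of these differences has a test.

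Among the features above the median level, the largest difference each way was as follows in each line. In BT474, MIMAT0006767 had a log2 signal of -0.51 without and 2.85 with trastuzumab, and MIMAT0000756 of 3.95 without and 0.40 with it. In SKBR3, MIMAT0004486 had 2.25 without and 7.24 with the antibody, and MIMAT0000231 had 7.28 and 2.01. In MCF7, MIMAT0003228 had 1.70 and 5.02, and MIMAT0000090 had 4.95 and 0.88. In MDA-MB-231, MIMAT0000428 had 1.49 and 5.07, and MIMAT0000231 had 5.996 and 2.63. With 16 added to the linear signal, the log2 differences of these features were 0.47 and -0.86 in BT474, 3.01 and -3.10 in SKBR3, 1.33 and -1.39 in MCF7 and 1.40 and -1.85 in MDA-MB-231, so both BT474 features lay under 2-fold. A scaled value below 0 arises from the centring of the bright BT474 arrays. The differences had an SD of 1.21 to 1.42 log2 in features with a mean at or below 3 and of 0.25 to 0.51 in features with a mean above 8.

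**Figure D1:**
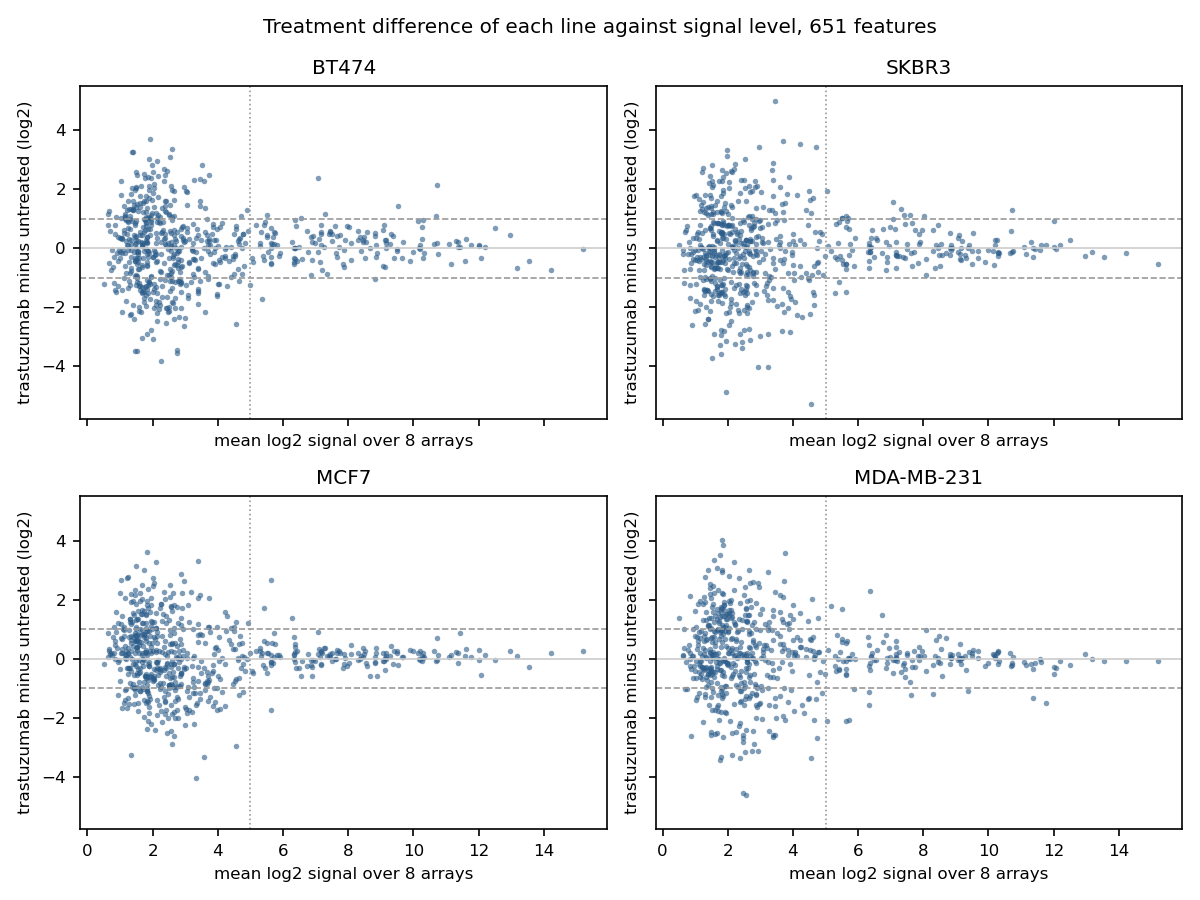
Difference in log2 signal between the trastuzumab and the untreated array of each line (vertical axis) against the mean log2 signal over the 8 arrays (horizontal axis), 1 point per tested feature. Dashed lines mark 2-fold and the dotted line a mean of 5. Past that mean, 4 to 15 of 151 features lie beyond 2-fold.

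The responses of the lines were then set against each other across the 151 brighter features. The log2 differences of BT474 and SKBR3 had a Pearson correlation of 0.44 and a Spearman correlation of 0.42. The other 5 of the 6 pairs of lines had Pearson correlations between -0.18 and 0.09. Among the 72 features with a mean above 8, the correlation of BT474 and SKBR3 was 0.52 and that of MCF7 and MDA-MB-231 was 0.04. These correlations are across features, which are not independent replicates, and the limits on the signal were chosen after seeing the data. Over all 651 features, the correlation of BT474 and SKBR3 was 0.02, and over the 325 features above the median it was 0.10. In both of these sets the pair of SKBR3 and MCF7 was higher, at 0.101 and 0.154. In the 151 brighter features 3 were more than 2-fold higher with trastuzumab in both BT474 and SKBR3, where independent lists of these sizes would share 0.51, and 0 were more than 2-fold lower in both. The largest of them, MIMAT0005880, differed by 2.37 in BT474 and 1.57 in SKBR3 against 0.89 in MCF7 and -0.06 in MDA-MB-231. The second, MIMAT0005898, with a mean log2 signal of 10.7, differed by 2.15 and 1.29 against 0.70 and -0.16. Both were chosen after their values were seen, and both had an adjusted p of 0.725 in limma's fit for SKBR3 and BT474.

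**Figure D2:**
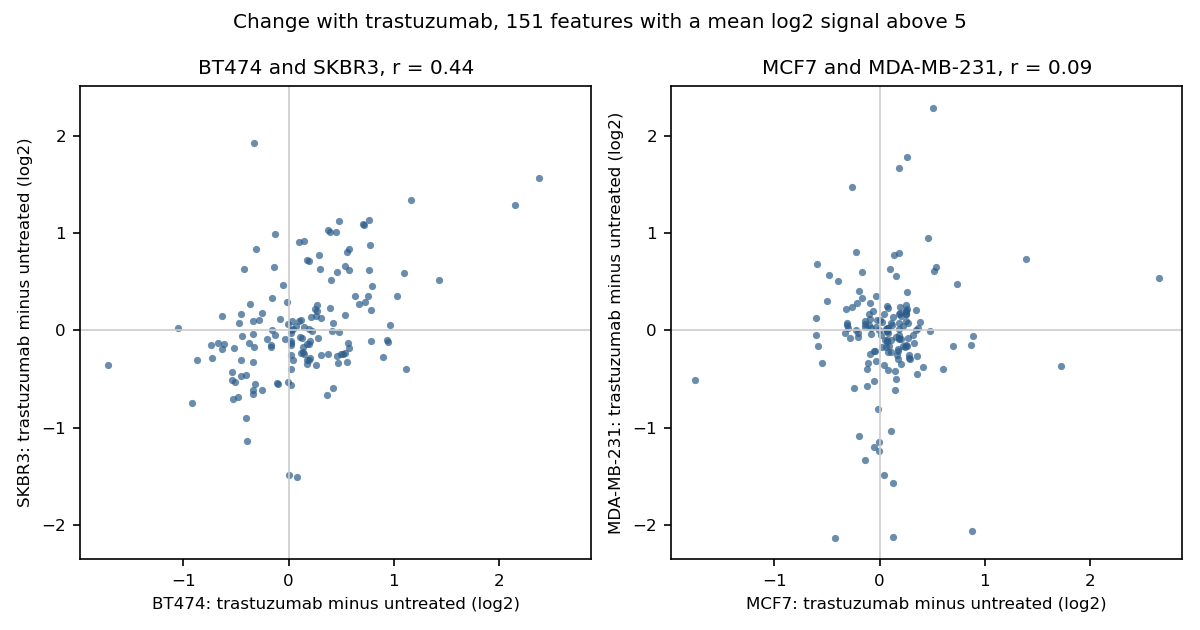
Change with trastuzumab in log2 signal of the 151 features with a mean log2 signal above 5, BT474 against SKBR3 on the left and MCF7 against MDA-MB-231 on the right, 1 point per feature. The Pearson correlation is 0.44 in the left panel and 0.09 in the right panel.

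The last comparisons concerned the lines themselves. MDA-MB-231 differed from the mean of BT474, SKBR3 and MCF7 in 69 of 651 features, 34 higher and 35 lower (limma, adjusted threshold 0.05). Both MDA-MB-231 arrays lay beyond all 6 other arrays in all 34 higher and in 32 of the 35 lower features. A call need not mean a clear difference from each line. The median change of the higher features was 9.59-fold and of the lower ones 10.5-fold, and 11 of the higher and 9 of the lower features passed 16-fold. The largest rise on this scale was in MIMAT0000279, which had a log2 signal of 11.1 ± 0.08 (SD, n = 2 arrays) in MDA-MB-231 and 2.56 ± 0.39 (SD, n = 6 arrays) in the other lines (log2 difference 8.51, SE 0.35, adjusted p = 0.000116). MIMAT0000278 had 12.01 ± 0.12 and 5.53 ± 0.60 (log2 difference 6.48, SE 0.38, adjusted p = 0.000469). The largest fall on this scale was in MIMAT0000432, which had 0.94 ± 0.49 in MDA-MB-231 and 11.3 ± 0.24 in the other lines (log2 difference -10.32, SE 0.40, adjusted p = 0.000116). MIMAT0000617 had 2.60 ± 0.01 and 11.4 ± 0.27 (log2 difference -8.77, SE 0.34, adjusted p = 0.000116). In 15 of the 34 higher features both MDA-MB-231 arrays exceeded a log2 signal of 5 while all arrays of the other lines stayed below it, and in 11 of the 35 lower features the reverse held. The deposited table gives no detection call, so a fold against a dim level depends on the background that the arrays retain. Adding 16 to the linear signal gave log2 differences of 6.62 for MIMAT0000279, 6.03 for MIMAT0000278, -7.10 for MIMAT0000432 and -6.91 for MIMAT0000617. Between the arrays with and without trastuzumab, these 4 features differed by -0.69 to 0.75 log2 in any line. The count of 69 was 114 when only features above the median were tested and 137 with the level-dependent, robust variance. It was 50 without BT474, 65 without SKBR3 and 62 without MCF7.

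**Figure D3:**
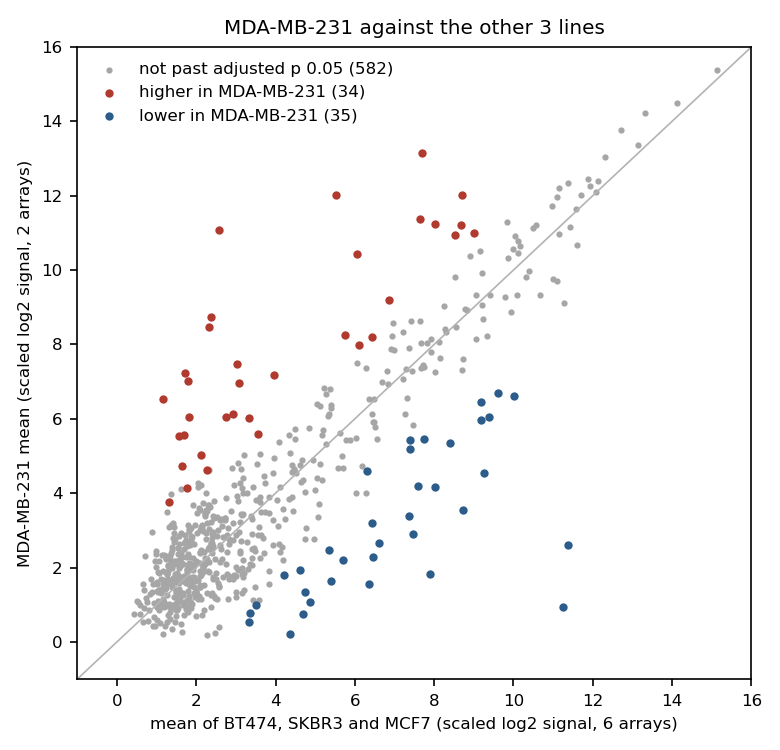
Mean scaled log2 signal in MDA-MB-231 (vertical axis, 2 arrays) against the mean of BT474, SKBR3 and MCF7 (horizontal axis, 6 arrays), 1 point per tested feature. Red points mark the 34 features higher in MDA-MB-231 and blue points the 35 lower, and the grey line marks equal signal.

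The last test set SKBR3 and BT474 against MCF7 and MDA-MB-231. With the line means as replicates (2 lines against 2), 0 of 651 features passed in limma and 28 stood at an unadjusted p under 0.05, against 32.6 expected by chance. Without MCF7 17 features passed and without MDA-MB-231 1 did, in fits where the remaining line of that class is assumed to vary like the other lines. In the fit of all 4 lines, the features with the smallest p that did not overlap between the classes were MIMAT0000281, with a log2 difference of 5.49 (adjusted p = 0.830), and MIMAT0000089, with 5.01 (adjusted p = 0.999). MIMAT0000281 had line means of 8.48 in SKBR3 and 5.85 in BT474 against 2.77 in MDA-MB-231 and 0.57 in MCF7. On the lower side, MIMAT0002809 had a log2 difference of -3.12 and MIMAT0000275 of -3.26 (adjusted p = 0.999 for both). MIMAT0000089 and MIMAT0000275 passed without MCF7 (log2 differences 5.60 and -4.54, adjusted p = 0.0324 and 0.0332), and MIMAT0000281 passed without MDA-MB-231 (6.60, adjusted p = 0.0179), while under the other alternatives the adjusted p of these 3 was 0.0568 or more. The log2 difference of MIMAT0000089 was 2.94 without SKBR3, and that of MIMAT0000275 was -1.99 without MDA-MB-231. Adding 16 to the linear signal gave log2 differences of 3.05 for MIMAT0000281, 2.26 for MIMAT0000089, -1.37 for MIMAT0002809 and -1.18 for MIMAT0000275. Over the 151 brighter features, the line means correlated best between BT474 and MCF7 (r = 0.86) and least between MCF7 and MDA-MB-231 (r = 0.52).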

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

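In 3 of the features named for the difference between the classes, both lines of one class moved one way and both lines of the other class the opposite way. These features were picked among those whose treatment differences did not overlap between the classes, so this pattern follows in part from the choice. How many of all tested features show it was not counted. The treatment difference of MIMAT0003236 was higher in SKBR3 and BT474 than in MCF7 and MDA-MB-231 by 3.12 log2. The treatment differences of MIMAT0005459 and MIMAT0002822 stood lower there, at -3.23 and -2.78 log2. None passed limma's test of the difference (adjusted p = 0.818 for each), and all were dim, with mean log2 signals of 1.43, 2.63 and 1.78. The differences were smaller with 16 added to the linear signal, at 0.57 for MIMAT0003236, -0.86 for MIMAT0005459 and -0.52 for MIMAT0002822.

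Outside the tested features, MIMAT0001536 stood out because it was bright in some lines and at the floor of 0 in others. Its deposited log2 signal was 8.35 and 8.10 on the BT474 arrays and 7.68 and 7.46 on the MCF7 arrays, and it was 0 on all 4 arrays of MDA-MB-231 and SKBR3. A search for single outlying samples was not made, since every group holds 1 array.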

How the results depend on the processing

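The limit of a mean above 5 and every correlation below were chosen after seeing the data. The count of 0 features for trastuzumab across the 4 lines stayed at 0 under every alternative except eBayes with trend and robust settings, which gave 2. In SKBR3 and BT474 that setting gave 3 and 2 when only features with a mean above 5 were tested. Without the cell line as a replicate block the count across lines was also 0, with 19 features at an unadjusted p under 0.05 instead of 46. For MCF7 and MDA-MB-231 and for the difference between the classes, all alternatives run gave 0. The 69 features called for MDA-MB-231 against the mean of the other lines became 114 among features above the median. With 16 added to the linear value there were 131, with trend and robust settings 137 and at a threshold of 0.10 110. All 69 were among the 131 and the 137. They are among the 110 by definition, since that count uses the same adjusted p with a wider limit. Without BT474 the count fell to 50, of which 48 were among the 69. Without SKBR3 it was 65, with 58 of the 69, and without MCF7 62, with 57 of the 69. The comparison of SKBR3 and BT474 with the other lines ranged from 0 to 17 features when a line was left out, with 17 reached without MCF7 and 1 without MDA-MB-231, in fits with 3 lines. Each of these fits leaves a single line in 1 class. Without MCF7, MDA-MB-231 alone was set against SKBR3 and BT474, and without MDA-MB-231, MCF7 alone was. Neither of these counts therefore speaks of the classes. Apart from the change of threshold, the cause of the other shifts was not tested. Numbers of features past 2-fold within BT474, SKBR3, MCF7 and MDA-MB-231 were 70, 97, 75 and 97 above the median level, where fewer features were counted, 6, 31, 9 and 34 with 16 added, which damps dim features, and 9, 14, 4 and 15 above a mean of 5. The correlation of the BT474 and SKBR3 differences was 0.102 above the median, 0.0189 over all tested features and 0.189 over all with 16 added. On the deposited scale the median difference was -0.12 in BT474 and -0.13 in MCF7, against 0.07 and 0.08 after centring. Of 343 alternative values of the named features, 0 changed sign and 5 passed the threshold newly. With 16 added, 28 of 32 were smaller by more than 1.5 times, and under all other alternatives 4 of 311 differed by more than that. Many of these values could not change, since settings that alter only the test, the threshold or the set of features return the same log2 differences. The named features were also picked for running one way or not overlapping. These counts of sign and size therefore say little on robustness. The tests of microRNA lists were not run, for want of names. Signal over background limits what the dim features can show.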

Other observations

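The tests of BT474, SKBR3 and MCF7 against the rest, the fits of the 151 brighter features, the tests of the correlation and of the most extreme feature, the counts of features that moved one way and the swaps within lines were chosen after the results were seen. Each line differed from the mean of the rest. Set against the mean of the remaining 3 lines, MCF7 differed in 35 features (20 higher, 15 lower) and BT474 in 30 (15 and 15). SKBR3 differed in 29 (13 and 16), next to 69 in MDA-MB-231 (limma, adjusted threshold 0.05). When only the 151 brighter features were tested, these counts were 92, 66, 64 and 95. Of the 205 features left out of the tests because they stood at the floor somewhere, 13 exceeded a log2 signal of 5 on some array and 7 on both arrays of a line.

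The brighter microRNAs were also tested apart from the dim ones. In a limma fit of the 151 brighter features alone, 25 stood at an unadjusted p under 0.05 in SKBR3 and BT474, 18 higher and 7 lower, where 7.55 are expected by chance. In MCF7 and MDA-MB-231 there were 8, and there were 14 for the difference between the classes and 9 for the effect across the 4 lines. In the fit of all 651 features, the same 151 gave fewer than 7.55 each time. There were 3 in SKBR3 and BT474, 0 in MCF7 and MDA-MB-231, 1 for the difference and 1 across the 4 lines. The counts among the brighter features therefore depend on the dim features fitted with them. The smallest adjusted p in SKBR3 and BT474 was 0.120 in the fit of the 151 alone and 0.725 in the fit of all 651, and for the difference it was 0.354 and 0.818, so 0 features passed in either. The features are not independent, so such a count can stray further from 7.55 than with independent features. Features that move alike in SKBR3 and BT474 also give the correlation of 0.44 between these lines. The count of 25 is therefore no separate evidence of a shared response. No swap of arrays was made for it.

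The differences of BT474 and SKBR3 correlated at 0.44 over the brighter features. A shared trend with signal level is argued against, since such trends held 2.61% of the variance of the differences in BT474 and 3.03% in SKBR3, which allows a correlation of at most 0.0281. A few features do not carry the correlation of 0.44 alone, since it was 0.322 without the 10 features that contribute most, with 0.048 the highest of the other pairs treated alike. A hybridisation or labelling difference common to the arrays of both lines stays open, since the correlation over the 389 features with a mean at or below 3 was -0.0432 but noise in dim features could hide a shared change there, and no label gives the order of processing. A response common to lines with amplified ERBB2 may be a further explanation, and it is a hypothesis that was not tested.

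MIMAT0000231 was lower with trastuzumab in all 4 lines, including those without amplified ERBB2, with scaled log2 signals of 4.31 to 7.73 without and 1.74 to 4.75 with the antibody. A difference between the treated and the untreated arrays that reaches many features stays open: 77 features moved one way in all 4 lines where 81.4 are expected (SD 8.44), but centring removes a common shift and noise in dim features could hide one. On the deposited scale, 6 features were past 2-fold the same way in all 4 lines and at most 3 in any other split, too few to decide. Array noise in the most extreme of 651 features stays open too: the smallest of its 4 differences was 2.57 log2 in size, and among the 8 splits that swap arrays within lines only the real one (1 of 8) reached that, the highest other being 1.54, but 8 splits are too few for a share under 0.05. An effect of the antibody on this feature stays open as well, since limma's test across the 4 lines gave an adjusted p of 0.378, and of 5.27e-07 with trend and robust settings. Those settings lean on a spread pooled over features of similar level, and their share of false calls was not simulated.

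For the count across the 4 lines, the real split gave 46 features at an unadjusted p under 0.05 and the highest other split gave 45. Of the 8 splits that swap arrays within lines, 1 was as large, the real one, and 8 splits are too few for a share under 0.05. In the adjusted test every split gave 0.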
